A study of Mus musculus with 12 samples.

How the data were processed

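The series holds 12 Illumina bead arrays of total RNA from primary mouse cardiac fibroblasts. The labels name 4 untreated control arrays, 4 CCN2 arrays (200 nmol/L) and 4 GDF15 arrays (500 nmol/L). The time of 48 h stands in the labels of the CCN2 and GDF15 arrays only. The control labels give no time, so whether culture time differed between control and treated cells could not be checked from them. Each array's group was taken from its title and its treatment label. The titles number the samples through all groups, so no number is shared between groups and no pairing was used. The labels do not say whether the 4 arrays of a group came from separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical.

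The deposited non-normalized table gives, per the file headers, a signal intensity and a detection p-value for each probe and array. The intensities were made with GenomeStudio 2010.1, per the submitters' processing notes. No deposited intensity lies below 0 and the column totals differ, so the intensities carry neither a background subtraction nor a scaling between arrays. The deposited detection p-value compares each probe with the negative control probes of its array. A second deposited table holds the authors' processed intensities. Its columns rank the probes exactly as the non-normalized columns do, and its sorted values lie within 0.392% of the mean of the sorted non-normalized columns, so it holds quantile-normalized intensities on a linear scale without background subtraction. Every column of it has a median of 42.4. The tool that made it and the array scanner settings are not given in the sources used here.

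Array brightness, the precision limit of such data, was read from the non-normalized table. The number of probes with a detection p-value under 0.05 was 19211 to 19691 on the control arrays, 18009 to 18979 on the CCN2 arrays and 19004 to 19481 on the GDF15 arrays. The number of arrays, 4 per group, limits the precision of each comparison. No 2 arrays held identical values.

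The non-normalized intensities were background-corrected with the normexp model, quantile-normalized and brought to the log2 scale with an offset of 16, using neqc in limma 3.58.1 under R 4.3.3. The offset makes changes of dim probes smaller than they are. Of 45281 probes, 20445 with a detection p-value under 0.05 on at least 4 of the 12 arrays were tested, and 24836 were left out. A group-means model was fitted to all 12 arrays with lmFit and eBayes, which leaves 9 residual degrees of freedom and gives all comparisons a common estimate of spread. CCN2 and GDF15 were each compared with control, and GDF15 with CCN2. All tests were two-sided. Benjamini-Hochberg adjustment ran over all tested probes of a comparison, with a threshold of 0.05. All adjusted p-values of single probes come from this limma fit.

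A probe that was detected on no array of a group has only a bound there. Its difference is given as "at least N-fold", from the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own value, all on the normalized log2 scale. For a probe detected on some arrays of a group, that number of arrays is given. Sizes without such a bound are log2 differences with the standard error (SE) of the fit.

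Gene names came from the platform's probe annotation, updated by gene ID through the RefSeq gene table of GRCm38.p6. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. The gene table held 34807 of the probes with 1 symbol, and no symbol changed. No coordinates are given because no genome build is named for the arrays' values. A gene is represented by its tested probe with the highest mean over all arrays, which gave 11018 genes, 4330 of them with over 1 tested probe. No probe is named here for the transcript of GDF15 itself, and its change after CCN2 is not reported here. The same holds for other list members without a named probe, which were not analysed here.

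Before the data were examined, the groups, tests, alternatives, the rule for named genes and 34 gene lists were written down: 25 lists of pathways and gene classes and 9 of cell type markers. For each treatment against control, the genes with the 10 largest increases and 10 largest decreases were named, among probes past the threshold whose 4 treated arrays all lay above, or all below, the 4 control arrays. For GDF15 against CCN2 the number was 8 each way. Up to 4 members with the largest change were named from each list among those past the threshold, or up to 2 where none passed. Ccn2, Gfral, Ret, Acta2, Col1a1 and Postn were always named. Predicted transcripts were not named. Members that moved against the rest of their list were named after their values were seen, and genes named in the closing section were too.

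Lists with at least 5 measured members, 31 of the 34, were tested with camera in limma, which asks whether a list moved relative to all other genes. It used a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment ran over the lists of a comparison. The test was repeated with the correlation estimated from the data, and with fry, which asks whether the members move on balance in 1 direction without comparing them with other genes. A list is said to shift, or not to, by camera, relative to other genes. Its adjusted p uses the preset correlation unless another is named. The estimated correlation was 0.1809 for the NF-kB inflammatory genes and 0.2337 for the G2 and M phase genes. Their shifts had far larger adjusted p with it. Counts of changed members use the adjustment over all probes. Where the adjustment over the list alone gives another count, both are given.

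Both treatments were set against the same 4 control arrays. Unchanged groups that share a simulated control group were therefore simulated 100 times, and the real controls were also split into 2 and 2 in 3 ways. The alternatives tried were no background correction, median scaling in place of quantile normalization, the authors' processed values, an offset of 50, no detection filter, a stricter filter, a fit of the compared groups alone, a trended robust variance model, array weights, 1 probe per gene before the fit, and leaving out each array in turn. Slide or chip positions were not analysed here.

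The fit was tested on 20 simulated data sets of 20445 probes for CCN2 against control, each with 200 changed probes. It recovered 4.3% of probes changed by 0.25 on the log2 scale, 57.9% of those changed by 0.5, 97.7% of those changed by 1 and 100% of those changed by 2. False calls made up 4.55% of calls. The real comparison called 10479 probes, far more than 200, so these shares do not give its sensitivity to small changes. A list shifted by 0.5 was recovered in 20 of 20 data sets. The simulated probes varied independently of each other, so this does not show how the list test behaves where members are correlated. Figures and files were handled with Python 3.11.15.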

Results

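Transcripts were measured on 12 arrays of cultured fibroblasts taken from the hearts of female C57/BL6 mice. CCN2, also called connective tissue growth factor, is a secreted matricellular protein, and GDF15 is a secreted member of the TGF-beta superfamily that signals through the receptor GFRAL with the co-receptor RET. 4 arrays held RNA of untreated cells, 4 of cells kept for 48 h with 200 nmol/L CCN2 and 4 of cells kept for 48 h with 500 nmol/L GDF15. The series title names GDF15 as a factor regulated by CCN2 in the heart, and the design sets each treatment against the untreated cells.

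The 3 groups formed separate clusters. Correlations of the normalized log2 values over the tested probes were 0.9869 to 0.9956 between arrays of 1 group, 0.9779 to 0.9834 between control and GDF15 arrays, 0.9482 to 0.9581 between CCN2 and GDF15 arrays and 0.9234 to 0.9278 between control and CCN2 arrays. The first principal component held 74.4% of the variance and placed the GDF15 arrays between the control and the CCN2 arrays. The second held 10.1% and set the GDF15 arrays apart from both. The third held 4.51% and placed replicates 1 and 3, numbered by title order within each group, above replicates 2 and 4 in every group. This order was not modelled, and its cause was not tested. The CCN2 arrays were dimmer before normalization: their 75th percentile of the signal was 77.5 ± 1.17 (SD, n = 4), against 90.4 ± 5.47 for control (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give, adjusted p = 0.0572 over 6 such tests). For the GDF15 arrays it was 87.4 ± 7.99 (exact permutation p = 0.571 against control).

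CCN2 against control compared cultures given the CCN2 preparation with untreated cultures. All 28 measured members of the list of NF-kB inflammatory genes rose (adjusted p = 4.35e-23, camera, and adjusted p = 0.00731 with an estimated correlation). Of the matrix proteins 21 of 31 fell, of the macrophage markers 17 of 23 and of the pericyte and smooth muscle markers 10 of 11 (adjusted p = 2.91e-05, 2.91e-05 and 3.76e-05). Il1b and Il1a, which encode interleukin-1 beta and alpha, were at least 256-fold and at least 125-fold higher and were detected on no control array. Timp3, an inhibitor of matrix proteases, was lower by 37.5-fold, and C1qc, a chain of complement C1q made by macrophages, by 34.2-fold. Of 20445 tested probes, 10479 (51.3%) changed, 5090 upward and 5389 downward, in 3140 and 3542 genes. Changes of at least 2-fold numbered 1114 upward and 1273 downward. The share of changed probes that rose was 48.6%, but 26.7% with median scaling in place of quantile normalization. That scaling brought the arrays to 1 median over all probes, tested or not. The median log2 change of the tested probes was then -0.17.

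Among the 10 genes with the largest increases, 7 were detected on no control array. Besides Il1b and Il1a these were the cystatin genes Cstdc4 (at least 223-fold) and Csta2 (at least 197-fold), Serpinb2, the inhibitor of plasminogen activators (at least 135-fold), the cornified envelope gene Sprr2e (at least 97.5-fold) and the decoy receptor gene Il13ra2 (at least 62.7-fold). The neutrophil chemokine Cxcl2 rose by 8.11 (SE 0.15) on the log2 scale and Acod1, which makes itaconate, by 6.31 (SE 0.12), each detected on 1 of 4 control arrays. Lcn2, the iron carrier lipocalin 2, rose by 6.72 (SE 0.20). Among the 10 genes with the largest decreases, Fcrls and the succinate receptor gene Sucnr1 were detected on no CCN2 array and were at least 45.6-fold and at least 37.4-fold lower. The log2 change was -5.78 (SE 0.086) for Gucy1a1, a subunit of the nitric oxide receptor, -5.23 (SE 0.096) for Timp3 and -5.14 (SE 0.090) for Pdlim3. It was -4.86 (SE 0.094) for the matrix gene Comp and -4.60 (SE 0.084) for the WNT antagonist Sfrp1. For Fgl2, detected on 2 of 4 CCN2 arrays, it was -5.06 (SE 0.16). Adjusted p for these 20 genes lay between 4.82e-18 and 7.77e-14, and in each all 4 CCN2 arrays lay above, or all below, the 4 control arrays.

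The 28 NF-kB inflammatory genes had a median log2 change of 3.27 (3.22 with undetected genes at their bound). Of 29 interferon-stimulated genes, 28 rose and 1 fell (adjusted p = 3.97e-13). The chemokine Cxcl10 rose by 3.28 (SE 0.12), the transcription factor Irf7 by 2.88 (SE 0.11), the ubiquitin-like modifier Isg15 by 2.84 (SE 0.11) and the GTPase Gbp2 by 2.67 (SE 0.10). Cxcl10 was detected on 1 of 4 control arrays. The interferon-stimulated gene that fell was Ifit2, at -0.65 (SE 0.12). The 11 genes of antigen presentation did not shift as a list (adjusted p = 0.453), with 6 higher and 4 lower. H2-Ab1 was higher by 2.76 (SE 0.15) and H2-K1 by 1.90 (SE 0.14), and H2-DMa was lower, at -1.51 (SE 0.092). On the same arrays the macrophage markers had a median log2 change of -1.39.

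Genes of glycolysis and hypoxia rose in all 21 measured members (adjusted p = 1.12e-14). Egln3, an oxygen-sensing hydroxylase, rose by 4.56 (SE 0.12), the glucose carrier Slc2a1 by 3.07 (SE 0.10), Vegfa by 2.43 (SE 0.077) and Pgk1 by 2.30 (SE 0.094). Of 29 genes of the unfolded protein and integrated stress response, 24 rose and 2 fell (25 and 2 adjusted over the list alone, adjusted p = 5.11e-07). Slc7a11, the cystine carrier, rose by 5.20 (SE 0.10) and Ddit4 by 1.88 (SE 0.077). Of 21 NRF2 antioxidant genes, 17 rose and 3 fell (adjusted p = 2.91e-05), with 2.66 (SE 0.091) for heme oxygenase Hmox1, 2.55 (SE 0.081) for Gclm and 2.41 (SE 0.086) for Srxn1. Of 18 genes of cholesterol synthesis, 13 rose and none fell (adjusted p = 0.00112, but adjusted p = 0.124 with an estimated correlation), the largest being Lss at 1.05 (SE 0.10) and Cyp51 at 0.83 (SE 0.10). Of 21 p53 targets, 14 rose and 6 fell (adjusted p = 0.0222, but adjusted p = 0.296 with an estimated correlation). The death receptor gene Fas rose by 1.62 (SE 0.076) and Gadd45a by 1.41 (SE 0.11), while Sesn1 changed by -2.23 (SE 0.11). Heat shock genes, with 9 of 15 higher and 2 lower (9 and 3 adjusted over the list alone), missed the threshold as a list (adjusted p = 0.0527, but adjusted p = 0.0463 with the authors' processed values and 0.0276 with median scaling), with 1.27 (SE 0.080) for Hspb8. The 23 genes of oxidative phosphorylation did not shift (adjusted p = 0.936): Cycs was higher at 0.48 (SE 0.090), and Cox4i1 and Sdhc were lower at -0.47 (SE 0.085) and -0.23 (SE 0.093) (1 higher and 1 lower adjusted over the list alone). The adjusted p of Sdhc was 0.0568 without the detection filter.

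Genes of the matrix and of the contractile fibroblast fell. Of 31 matrix proteins, 21 fell and 3 rose (adjusted p = 2.91e-05). Elastin, Eln, changed by -4.43 (SE 0.10) and Col14a1 by -3.20 (SE 0.077), while the proteoglycan Vcan, detected on 3 of 4 control arrays, rose by 3.22 (SE 0.13). The other matrix genes that rose were Thbs1 at 1.62 (SE 0.085) and Tnc at 1.28 (SE 0.13). The main fibrillar collagen gene Col1a1 was at -0.14 (SE 0.11) (adjusted p = 0.313) and passed no threshold. Postn, the matricellular periostin, fell by 0.96 on the log2 scale (SE 0.13) and was detected on 3 of 4 CCN2 arrays. Of 20 contractile genes of myofibroblasts, 13 fell and 2 rose (adjusted p = 0.00443, but adjusted p = 0.0983 with an estimated correlation). The smooth muscle actin Acta2 changed by -1.43 (SE 0.085), Myl9 by -2.39 (SE 0.082), Actg2 by -2.03 (SE 0.12) and Vcl by -1.74 (SE 0.11). Of 17 fibroblast markers, 12 fell and 1 rose (12 and 2 adjusted over the list alone, adjusted p = 0.000284), with -2.69 (SE 0.099) for the transcription factor Tcf21 and -2.31 (SE 0.11) for Dpt. The marker that rose was P4hb, at 0.70 (SE 0.093). Of 19 genes of collagen processing and crosslinking, 10 rose and 5 fell (adjusted p = 0.0331, but adjusted p = 0.202 with an estimated correlation and 0.0566 with the stricter detection filter). The prolyl hydroxylase P4ha2 rose by 2.68 (SE 0.087) and the lysyl oxidase Lox by 1.75 (SE 0.073). The 21 matrix proteases and inhibitors did not shift as a list (adjusted p = 0.323), with 9 higher and 7 lower: Mmp9 and Mmp13 rose by 5.09 (SE 0.13) and 4.34 (SE 0.10), and Mmp11 changed by -3.06 (SE 0.087). Of 5 bone and cartilage genes, 4 fell (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.00122, which became 0.106 without the detection filter), including the matrix Gla protein Mgp at -3.61 (SE 0.086) and Ogn at -3.41 (SE 0.11).

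The transcript of Ccn2 itself fell by 2.07 on the log2 scale (SE 0.085, adjusted p = 1.74e-12) after the protein was added, from 13.81 ± 0.08 to 11.74 ± 0.11 (SD, n = 4, exact permutation p = 0.0286). Of the 13 genes of the CCN and IGFBP family, 11 fell and none rose (adjusted p = 2.11e-05), including Igfbp4 at -4.48 (SE 0.11), Igf2 at -3.94 (SE 0.11) and Ccn5 at -3.66 (SE 0.086). Of 9 BMP SMAD1/5 targets, 7 fell and 2 rose (adjusted p = 0.00656). Smad6, an inhibitor of BMP signals, changed by -2.36 (SE 0.11), Hey1 by -2.14 (SE 0.11) and Id1 by -1.48 (SE 0.088), and Id4 was at least 6.03-fold lower and detected on no CCN2 array. The 20 TGF-beta SMAD2/3 targets split, with 9 higher and 10 lower (adjusted p = 0.827): Itga11 changed by -3.28 (SE 0.098) and Tgfb3 by -2.16 (SE 0.13), while Inhba rose by 2.07 (SE 0.14). The 23 SRF and YAP immediate genes did not pass as a list (adjusted p = 0.0651), with 10 higher and 5 lower, led by Ier3 at 4.08 (SE 0.098). Of 22 ligands and receptors of the treatments, 6 rose and 7 fell (adjusted p = 0.827), with a median of -0.033 and a mean of 0.061. The integrin gene Itgav rose by 2.11 (SE 0.11), and Ret was detected on all 4 CCN2 arrays and on no control or GDF15 array, at least 1.89-fold higher than in control. Gfral was detected on none of the 12 arrays. Lists with members on both sides and no shift were the WNT pathway (3 higher, 8 lower of 13, or 4 and 8 adjusted over the list alone, adjusted p = 0.104), adipogenic genes (5 higher, 8 lower of 15, adjusted p = 0.827) and angiogenic and growth factors (9 higher, 6 lower of 21, adjusted p = 0.203). Named members were Sfrp2 at -3.70 (SE 0.14), Angptl4 at 3.63 (SE 0.11), Pparg at -1.57 (SE 0.089), Vegfd at -3.46 (SE 0.084) and the RET ligand Gdnf at 2.94 (SE 0.11). The median log2 change of the adipogenic list was -0.30 (-0.0064 with undetected genes at their bound) and its mean 0.15.

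Cell cycle genes fell. Of 23 S phase genes, 21 fell and 1 rose (adjusted p = 1.15e-07), led by the thymidine kinase Tk1 at -2.27 (SE 0.12) and the replicative helicase genes Mcm6 at -1.73 (SE 0.11) and Mcm5 at -1.71 (SE 0.099). The gene that rose was the thymidylate synthase Tyms, at 0.38 (SE 0.090), a call that median scaling ended (adjusted p = 0.199). Of 18 G2 and M phase genes, 16 fell and none rose (adjusted p = 6.52e-07, but adjusted p = 0.0628 with an estimated correlation), with -1.72 (SE 0.13) for Birc5 and -1.50 (SE 0.11) for Cdca8.

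Markers of other cell types in the cultures moved too. Of 23 macrophage markers, 17 fell and 3 rose (17 and 4 adjusted over the list alone, adjusted p = 2.91e-05). C1qc changed by -5.10 (SE 0.098), C1qb by -4.81 (SE 0.084), C1qa by -3.93 (SE 0.10) and the mannose receptor Mrc1 by -3.59 (SE 0.12). The markers that rose were the lectin genes Clec4n at 2.48 (SE 0.080) and Clec4d at 0.88 (SE 0.10) and the endotoxin co-receptor Cd14 at 0.98 (SE 0.077). Of 16 endothelial markers, 14 fell and 1 rose (15 and 1 adjusted over the list alone, adjusted p = 2.07e-05), led by Cldn5 at -1.57 (SE 0.11) and Sox18 at -1.41 (SE 0.10), and Eng rose by 0.25 (SE 0.095), with overlap between the groups, a call that median scaling ended (adjusted p = 0.686). Of 11 pericyte and smooth muscle markers, 10 fell (adjusted p = 3.76e-05), led by Pdlim3 and by Notch3 at -3.20 (SE 0.093). The cardiomyocyte markers (2 higher, 7 lower of 11, adjusted p = 0.124) and the epicardial and mesothelial markers (4 higher, 4 lower of 9, adjusted p = 0.869) did not shift as lists. Named members were Nppa at -1.85 (SE 0.12), Aldh1a1 at -3.75 (SE 0.13) and Aldh1a2 at 2.56 (SE 0.11). Too few Schwann and neural markers (4), lymphocyte markers (2) and erythroid markers (1) were measured to test those lists. Of these, Mbp changed by -1.34 (SE 0.10) and Cnp by -0.62 (SE 0.092), Cd79b was at least 1.21-fold lower and Hbb-bt, detected on 1 of 4 control and 1 of 4 CCN2 arrays, was at 0.08 (SE 0.11) (adjusted p = 0.569).

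**Figure D1:**
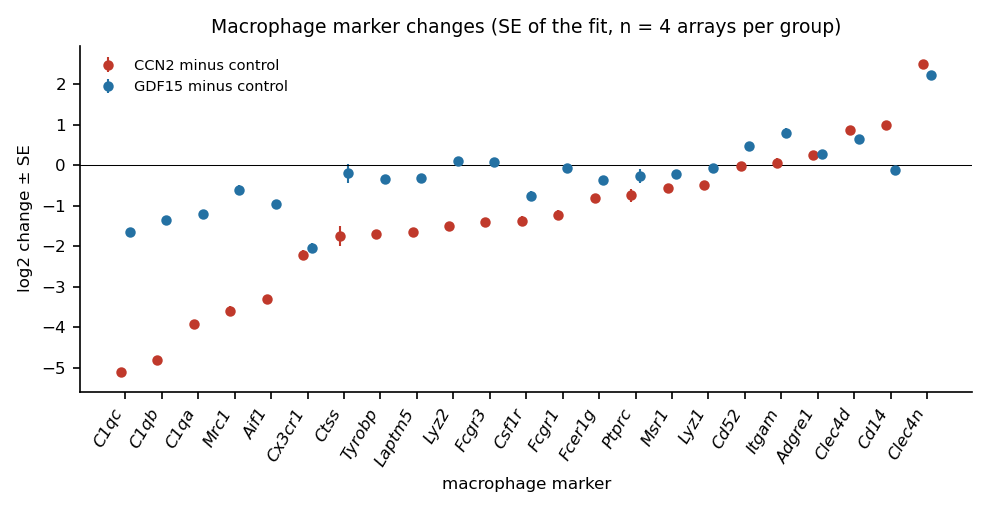
Log2 change (vertical axis) of the 23 measured macrophage markers (horizontal axis), ordered by their change after CCN2; points are the fitted changes against control and whiskers the SE of the fit (n = 4 arrays per group). After CCN2 the changes ran from -5.10 for C1qc to 2.48 for Clec4n, and Clec4n was also the marker with the highest change after GDF15.

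In all, 19 lists shifted after CCN2, 8 up and 11 down, and 14 of them held with an estimated correlation. Each of the 3 groups holds 4 arrays, and 48.5% of probes had all CCN2 arrays on 1 side of all control arrays, against 2.86% by chance.

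**Figure D2:**
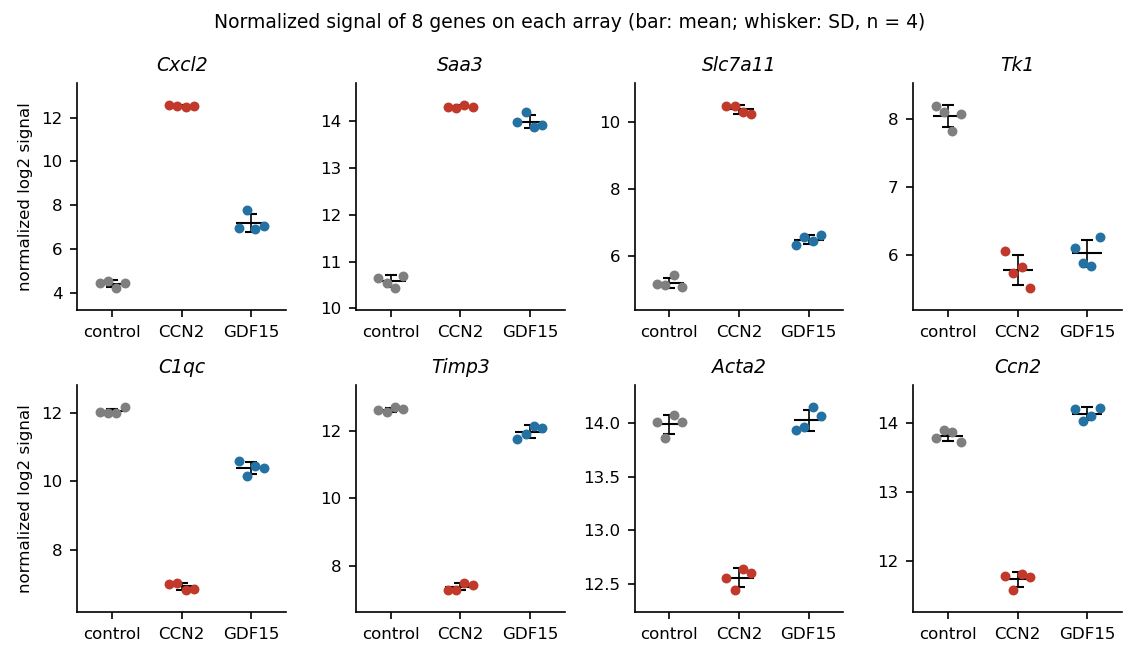
Normalized log2 signal (vertical axis) of 8 genes on each array, by group (horizontal axis); points are arrays, the bar is the group mean and the whisker its SD (n = 4). Cxcl2, Saa3 and Slc7a11 were higher and Tk1 and C1qc lower after both treatments, Timp3 was lower by 5.23 on the log2 scale after CCN2 and by 0.64 after GDF15, and Ccn2 lay at 11.74 after CCN2 against 13.81 in control and 14.13 after GDF15.

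GDF15 against control compared cultures given the GDF15 preparation with the same untreated cultures. Fewer probes changed than after CCN2, and 23 of 28 NF-kB inflammatory genes rose (adjusted p = 3.09e-27, and adjusted p = 0.00446 with an estimated correlation). The chemokine Ccl5 was 17.4-fold higher and the acute phase gene Saa3 10.7-fold higher. Of 23 S phase genes, 22 fell (adjusted p = 3.15e-20, and adjusted p = 0.000556 with an estimated correlation), with Tk1 lower by 4.08-fold. Of 20445 tested probes, 4088 (20%) changed, 1909 upward and 2179 downward, in 1249 and 1577 genes. Changes of at least 2-fold numbered 219 upward and 204 downward. The share that rose was 46.7%, and 34.5% with median scaling, where the median log2 change of the tested probes was -0.052.

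Among the 10 genes with the largest increases, Csta2 and Cstdc4 were detected on no control array and were at least 15.9-fold and at least 11.9-fold higher. Ccl5 rose by 4.12 (SE 0.17) on the log2 scale, Lcn2 by 3.55 (SE 0.20), Saa3 by 3.41 (SE 0.090) and the calprotectin subunit S100a8 by 3.25 (SE 0.078). The SD of Ccl5 and Lcn2 was 0.47 and 0.56 on the GDF15 arrays, against 0.06 and 0.07 on the CCN2 arrays. Their SE rests on the common estimate of spread, which is narrow for them on the GDF15 arrays. The protease inhibitor Slpi, detected on 1 of 4 control arrays, rose by 3.71 (SE 0.086), and the nonclassical class I gene H2-M2, detected on 2, by 2.97 (SE 0.15). The formyl peptide receptor Fpr2 rose by 3.18 (SE 0.11) and the gelatinase Mmp9 by 3.09 (SE 0.13). Among the decreases, Inmt was at least 9.38-fold lower and detected on no GDF15 array. Fcrls changed by -3.41 (SE 0.092), the growth factor Ptn by -3.05 (SE 0.099), Scg2 by -2.76 (SE 0.11), the complement receptor Vsig4 by -2.59 (SE 0.11) and Fgl2 by -2.56 (SE 0.16). The matrix-associated genes Htra3, Matn4 and Cthrc1 changed by -2.25 (SE 0.12), -2.23 (SE 0.14) and -2.11 (SE 0.12), and the carrier Slco2b1 by -2.24 (SE 0.088). Adjusted p for these 20 genes lay between 3.44e-14 and 5.38e-09, and in each all 4 GDF15 arrays lay on 1 side of all 4 control arrays.

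Of 28 NF-kB inflammatory genes, 23 rose and none fell (24 and none adjusted over the list alone, adjusted p = 3.09e-27), with a median log2 change of 1.15 (1.09 with undetected genes at their bound). Cxcl2, detected on 1 of 4 control arrays, rose by 2.76 (SE 0.15). Of 29 interferon-stimulated genes, 22 rose and none fell (24 and none adjusted over the list alone, adjusted p = 2.69e-20), led by Irf7 at 2.33 (SE 0.11), Isg15 at 1.96 (SE 0.11), Gbp3 at 1.84 (SE 0.099) and the antiviral synthetase Oas2 at 1.77 (SE 0.13). The genes of antigen presentation did not shift as a list (adjusted p = 0.318), with 4 higher and 2 lower (4 and 3 adjusted over the list alone), H2-K1 being higher by 1.18 (SE 0.14). Of 21 matrix proteases and inhibitors, 10 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.00179). Mmp13 rose by 1.94 (SE 0.10) and the inhibitor Timp1 by 1.97 (SE 0.11), while Mmp11 changed by -1.40 (SE 0.087).

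Of 23 SRF and YAP immediate genes, 13 rose and none fell (14 and none adjusted over the list alone, adjusted p = 6.27e-09): Fos by 1.47 (SE 0.11), Egr1 by 1.27 (SE 0.090), Ier3 by 1.15 (SE 0.098) and the cardiac ankyrin repeat gene Ankrd1 by 1.14 (SE 0.099). Of 20 TGF-beta SMAD2/3 targets, 9 rose and 2 fell (9 and 4 adjusted over the list alone, adjusted p = 0.00518), including Inhba, a subunit of activin, at 1.66 (SE 0.14), Junb at 1.18 (SE 0.081) and Spsb1 at 1.03 (SE 0.083). The Ccn2 transcript rose slightly, by 0.32 (SE 0.085) (adjusted p = 0.0132), to 14.13 ± 0.09 (SD, n = 4, exact permutation p = 0.0286). The CCN and IGFBP family did not shift (adjusted p = 0.557), with 4 higher and 4 lower, led by Ccn4 at 1.37 (SE 0.10). The BMP SMAD1/5 targets did not shift either (adjusted p = 0.903), and 1 of 9 passed, Hey1 at -1.10 (SE 0.11). Their median was 0.13 and their mean -0.061. Among ligands and receptors of the treatments, 4 of 22 were higher and 1 lower (6 and 2 adjusted over the list alone, adjusted p = 0.0826), with 0.85 (SE 0.093) for the BMP receptor Bmpr2. Ret and Gfral were detected on no GDF15 array.

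Of 23 S phase genes, 22 fell and none rose (23 fell adjusted over the list alone, adjusted p = 3.15e-20), including Tk1 at -2.03 (SE 0.12), Mcm5 at -1.71 (SE 0.099) and Uhrf1 at -1.51 (SE 0.099). Of 18 G2 and M phase genes, 16 fell and none rose (adjusted p = 8.75e-17, and adjusted p = 0.0151 with an estimated correlation), with -1.59 (SE 0.094) for Nusap1 and -1.57 (SE 0.11) for Cenpa. Genes of glycolysis and hypoxia rose in 13 of 21 members and fell in 1 (14 and 1 adjusted over the list alone, adjusted p = 1.9e-05), led by Egln3 at 0.99 (SE 0.12), and Ndrg1 changed by -0.64 (SE 0.083). Of 29 genes of the unfolded protein and integrated stress response, 6 rose and none fell (7 and none adjusted over the list alone, adjusted p = 0.0079, but adjusted p = 0.139 with an estimated correlation), led by Slc7a11 at 1.30 (SE 0.10). The NRF2 antioxidant genes (5 higher, 1 lower of 21, adjusted p = 0.0818), p53 targets (3 higher, 4 lower of 21, adjusted p = 0.476), heat shock genes (2 higher of 15, adjusted p = 0.179), genes of cholesterol synthesis (1 higher, 1 lower of 18, none of them adjusted over the list alone, adjusted p = 0.363) and of oxidative phosphorylation (none of 23, adjusted p = 0.778) did not shift as lists. Named members were Hmox1 at 0.80 (SE 0.091), Plk2 at 0.82 (SE 0.095), Hspa1b at 0.65 (SE 0.17), with overlap between the groups, and Insig1 at 0.77 (SE 0.25). Without the detection filter the adjusted p of Hspa1b was 0.0573 and that of Insig1 0.165. Cox4i1 was at -0.16 (SE 0.085) and Ndufa4 at -0.15 (SE 0.078), neither past the threshold.

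Matrix genes fell in part. Of 31 matrix proteins, 13 fell and 2 rose (adjusted p = 0.00728, but adjusted p = 0.178 with an estimated correlation and 0.105 with median scaling), with -2.08 (SE 0.094) for Comp, -1.89 (SE 0.10) for Eln and -1.48 (SE 0.17) for Tnxb. Of 17 fibroblast markers, 6 fell and none rose (7 fell and 1 rose adjusted over the list alone, adjusted p = 0.0302, but adjusted p = 0.0861 with an estimated correlation and 0.1 with median scaling), led by Clec3b at -1.69 (SE 0.12). The contractile genes of myofibroblasts did not shift (adjusted p = 0.601), with 3 higher and 2 lower of 20. Tagln was higher at 0.52 (SE 0.088), Cald1 was higher at 0.81 (SE 0.26), with overlap between the groups and adjusted p = 0.156 without the detection filter, and Myh11 was lower at -0.74 (SE 0.13). Acta2, Col1a1 and Postn passed no threshold, at 0.04 (SE 0.085), 0.02 (SE 0.11) and 0.15 (SE 0.13). Genes of collagen processing (6 higher, 2 lower of 19, or 6 and 3 adjusted over the list alone, adjusted p = 0.0826), of the WNT pathway (3 higher, 4 lower of 13, adjusted p = 0.601), adipogenic genes (2 higher, 1 lower of 15, adjusted p = 0.601) and angiogenic and growth factors (9 higher, 3 lower of 21, or 9 and 5 adjusted over the list alone, adjusted p = 0.0826) did not shift as lists. Lox rose by 0.77 (SE 0.073), Nkd2 by 0.92 (SE 0.11), Edn1, which encodes endothelin-1, by 1.18 (SE 0.12) and Bdnf by 1.13 (SE 0.10), and Pparg changed by -0.88 (SE 0.089). The median of the adipogenic list was -0.0081 and its mean 0.02. Of 5 bone and cartilage genes, 3 fell (3 lower and 2 higher adjusted over the list alone, adjusted p = 0.0264, but adjusted p = 0.0864 with an estimated correlation, 0.501 without the detection filter and 0.0527 with median scaling), led by Omd at -1.43 (SE 0.084).

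Of 23 macrophage markers, 10 fell and 4 rose after GDF15 (11 and 5 adjusted over the list alone, adjusted p = 0.0415, but adjusted p = 0.217 with an estimated correlation and 0.125 with median scaling). The lectin Clec4n rose by 2.21 (SE 0.080). The fractalkine receptor Cx3cr1, detected on 2 of 4 GDF15 arrays, changed by -2.04 (SE 0.13), C1qc by -1.65 (SE 0.098) and C1qb by -1.35 (SE 0.084). The list's adjusted p was 0.0866 without GDF15 replicate 3, and 0.0514 and 0.0523 without CCN2 replicates 1 and 4, which enter the common estimate of spread. Of 11 pericyte and smooth muscle markers, 5 fell (7 adjusted over the list alone, adjusted p = 0.00271, but adjusted p = 0.104 with an estimated correlation), led by Vtn, detected on 2 of 4 GDF15 arrays, at -0.95 (SE 0.10) and Notch3 at -0.74 (SE 0.093). The endothelial markers did not shift (1 lower of 16, Cldn5 at -0.46 (SE 0.11), adjusted p = 0.601), nor did the cardiomyocyte markers (2 lower of 11, or 3 adjusted over the list alone, adjusted p = 0.351) and the epicardial and mesothelial markers (2 higher of 9, adjusted p = 0.197). Csrp3 was at least 1.12-fold lower and Aldh1a2 higher at 0.98 (SE 0.11). Of the markers too few to test as lists, Mbp was at -0.28 (SE 0.10) and Cnp at -0.24 (SE 0.092) (neither past the threshold, both past it adjusted over the list alone), Cd79b, detected on 1 of 4 GDF15 arrays, changed by -0.42 (SE 0.093), and Hbb-bt, detected on 2 of 4 GDF15 arrays, was at 0.12 (SE 0.11) and passed no threshold.

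In all, 14 lists shifted after GDF15, 7 up and 7 down, and 8 of them held with an estimated correlation. All GDF15 arrays lay on 1 side of all control arrays for 22.8% of probes, against 2.86% by chance.

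**Figure D3:**
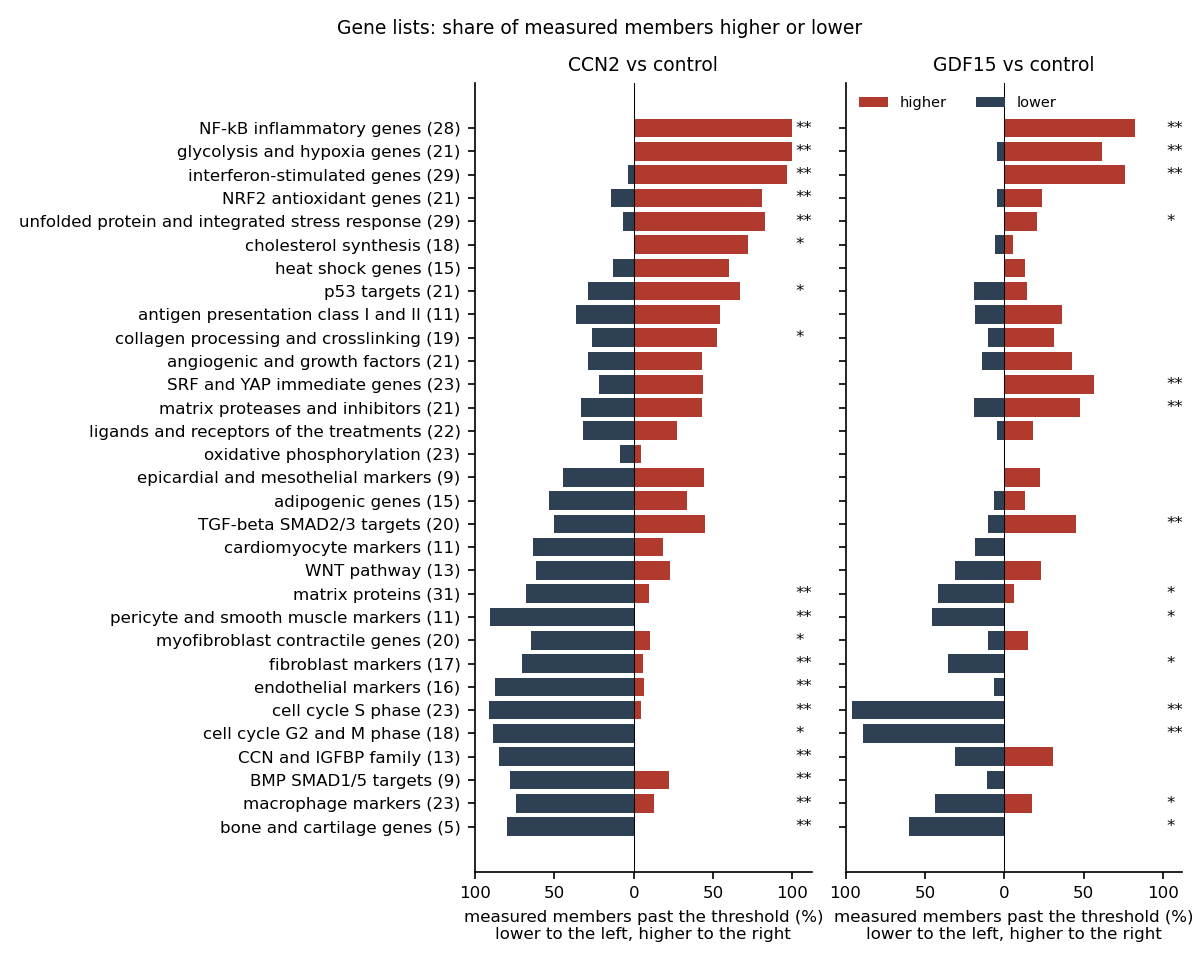
Share of the measured members (in %, number of members in brackets) of each tested list that were higher (right) or lower (left) after CCN2 and after GDF15, each against control; lists are ordered by their median log2 change after CCN2. An asterisk marks a list shift past the threshold with camera and 2 asterisks one that also held with an estimated correlation: 14 of 19 shifts after CCN2 and 8 of 14 after GDF15.

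GDF15 against CCN2 tested the difference between the treatments itself, at doses that differed (500 and 200 nmol/L). Of the NF-kB inflammatory genes 27 of 28 were lower after GDF15 than after CCN2 (adjusted p = 3.01e-19, and adjusted p = 0.0162 with an estimated correlation). Of the endothelial markers 15 of 16 were higher (adjusted p = 2.94e-07, and adjusted p = 0.025 with an estimated correlation). In this comparison 8534 probes (41.7%) differed, 4262 higher and 4272 lower after GDF15. The share that was higher was 49.9%, and 72.1% with median scaling, where the median log2 difference of the tested probes was 0.12. The genes higher after GDF15 by the largest amounts were Pdlim3 (4.86 (SE 0.090)), Gucy1a1 (4.85 (SE 0.086)), Timp3 (4.59 (SE 0.096)), the hyaluronan-degrading Cemip (4.42 (SE 0.10)), Msc (3.84 (SE 0.089)), Sfrp1 (3.79 (SE 0.084)) and the retinal dehydrogenase Aldh1a1 (3.75 (SE 0.13)), and Sucnr1, at least 15.7-fold higher. The genes lower by the largest amounts were Serpinb2 (-7.12 (SE 0.12), detected on 2 of 4 GDF15 arrays), Il1b (-6.95 (SE 0.22)), Cxcl2 (-5.35 (SE 0.15)), Il13ra2 (-5.18 (SE 0.13)) and Il1a (-5.07 (SE 0.11)). Sprr2e and the colony-stimulating factors Csf2 and Csf3 were detected on no GDF15 array and were at least 96.5-fold, 43.1-fold and 26.8-fold lower.

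Between the treatments 18 lists differed, 10 higher and 8 lower after GDF15. Of 28 NF-kB inflammatory genes, 27 were lower and 1, Ccl20, was higher at 1.07 (SE 0.14) (adjusted p = 3.01e-19), of 21 genes of glycolysis and hypoxia all 21 were lower (adjusted p = 1.44e-16), and of 13 genes of the CCN and IGFBP family 12 were higher (adjusted p = 1.18e-08). Of 31 matrix proteins, 20 were higher and 5 lower (adjusted p = 2.16e-05), of 20 contractile genes 12 were higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.000212) and of 16 endothelial markers 15 were higher (adjusted p = 2.94e-07). Macrophage markers were higher in 18 of 23 and lower in 2 (18 and 3 adjusted over the list alone, adjusted p = 2.94e-07). The cell cycle lists did not differ relative to other genes: 7 of 23 S phase genes were higher and 2 lower (6 and 1 adjusted over the list alone, adjusted p = 0.528 with camera, but higher on balance with fry, adjusted p = 0.0199), and 1 of 18 G2 and M phase genes was higher and 1 lower (none adjusted over the list alone, adjusted p = 0.664). The shifts of collagen processing (adjusted p = 0.04), cholesterol synthesis (3.41e-05) and p53 targets (0.00626) did not hold with an estimated correlation, with adjusted p = 0.235, 0.0622 and 0.237. That of collagen processing also ended without GDF15 replicate 4 (adjusted p = 0.0546).

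The 2 responses overlapped. Of 3434 probes changed after both treatments, 3254 (94.8%) changed the same way, 1397 upward and 1857 downward, where independent lists of these sizes would give 475 and 574. Unchanged groups simulated with a shared control group gave a mean of 0 shared calls. Groups without effects are bound to give almost no calls, so this is no expected overlap of 2 real responses. With each treatment set against its own 2 control arrays, 2051 to 2208 probes changed the same way. Over all tested probes the log2 changes had a covariance of 0.177, against 0.0073 simulated for unchanged groups, a difference of 0.17, and with split controls it was 0.166 to 0.176. Their correlation across probes, which are not independent replicates, was 0.667, and 0.596 to 0.657 with split controls. Shared controls alone gave 0.5 in the simulated groups without effects. That value is not the part of 0.667 that comes from shared controls. Among probes changed the same way, 82.8% had the larger change after CCN2, and the median ratio of the GDF15 to the CCN2 change was 0.586. Only probes past the threshold after both treatments enter these 2 values, which favours large GDF15 changes. Over all tested probes the variance of the log2 changes was 0.588 after CCN2 and 0.12 after GDF15.

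Another 180 probes changed in opposite directions, 143 of them lower after CCN2 and higher after GDF15 and 37 the reverse. With split controls 90 to 171 probes changed in opposite directions. In 33 of the 102 named genes among them both changes were at least 0.5 on the log2 scale. The following genes were chosen from those after their values were seen. The homeobox gene Gbx2, detected on 2 of 4 CCN2 arrays, changed by -1.29 (SE 0.14) after CCN2 and by 2.30 (SE 0.14) after GDF15. The serpin genes Serpina3n and Serpina3f changed by -1.58 (SE 0.10) and -0.89 (SE 0.094) after CCN2 and by 1.10 (SE 0.10) and 2.19 (SE 0.094) after GDF15. The alarmin Il33 changed by -2.34 (SE 0.12) and 0.98 (SE 0.12), the immediate early gene Fos by -0.87 (SE 0.11) and 1.47 (SE 0.11), and the urokinase Plau by -2.06 (SE 0.11) and 0.65 (SE 0.11). In the reverse direction the transferrin receptor Tfrc changed by 1.07 (SE 0.084) and -0.56 (SE 0.084) and the water channel Aqp1 by 0.95 (SE 0.091) and -0.70 (SE 0.091).

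**Figure D4:**
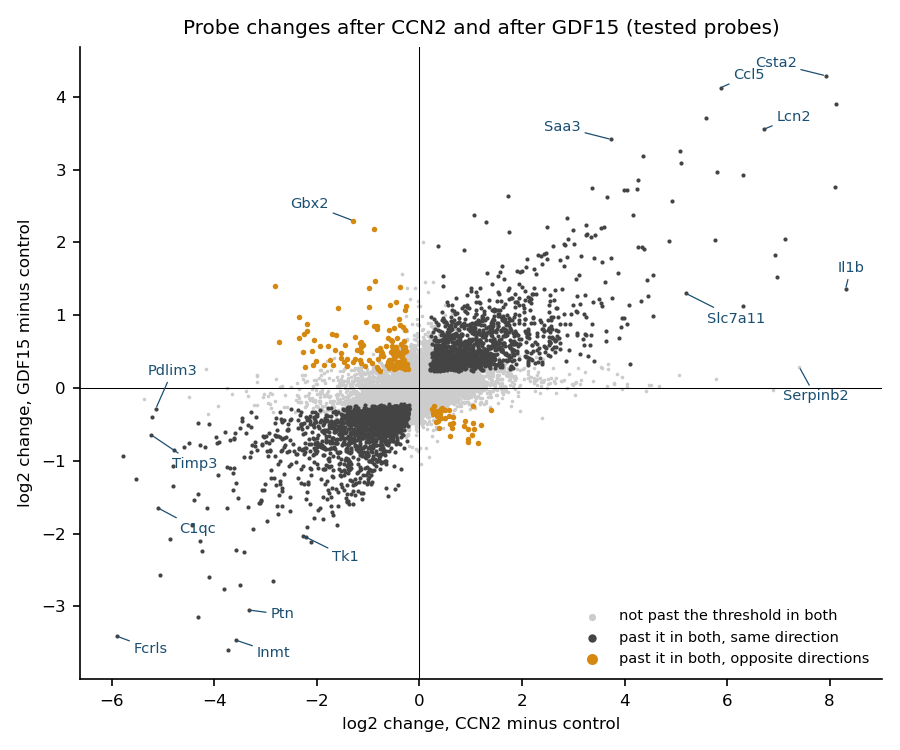
Log2 change of each tested probe after CCN2 (horizontal axis) and after GDF15 (vertical axis), both minus control. Dark points passed the threshold in both comparisons in the same direction (3254 probes), orange points in opposite directions (180 probes), and pale points did not pass in both.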

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

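Of the tests below, the expression-matched random lists for the cell cycle and the macrophage markers were set before their results were seen, and the regroupings of arrays, the counts of opposite probes, the limit set for the planned splits of the controls and the spread of the macrophage markers were chosen only after the result was seen.

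The counts of changed probes were set against other splits of the 8 arrays of each comparison into 4 and 4, 35 in all. In each comparison 1 of the 35 splits, the real one, gave as many changed probes, the smallest share that such splits can give: 10479 against 0 for the highest other split after CCN2, 4088 against 1 after GDF15, and 8534 against 1 between the treatments. The other splits carry the difference between the groups into their spread, which lowers their counts. A random split of these arrays does not account for the real counts. The spread between the arrays may be technical, so chance between cultures is not excluded. The number of shifted lists was 14 after GDF15 and 18 between the treatments, against 12 and 17 in the highest other split, and 1 of 35 splits gave as many in each case. After CCN2 the real split gave 19 lists and so did 1 other, making 2 of 35 splits, so the number of lists does not exclude chance by itself. It follows how far a split keeps the treatment together: the 16 splits with 3 of the 4 CCN2 arrays on 1 side gave 14 to 19 lists, and the 18 splits with 2 on each side gave 0 to 1. For probes changed the same way by both treatments, 2 of 100 regroupings of the 12 arrays into 3 groups of 4 gave as many as the real 3254. The other 1 gave 6876 and had all 4 CCN2 arrays as its reference group, and the next highest gave 0. A count above the real one thus arose with only the CCN2 arrays kept together. These regroupings test neither the overlap itself nor the difference between GDF15 and control.

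The first pattern was a shared response to both treatments, with 23 of 28 NF-kB inflammatory genes higher in both. Chance differences between the control arrays shared by both comparisons do not account for all of it. The lowest covariance with split controls was 0.1662, and the highest simulated covariance was 0.0077. A trait common to all control arrays stays in every split, so these values cannot exclude it as a cause. A single agent in both protein preparations acting the same way at 2 strengths is open for the probes that changed the same way. It is excluded only as the whole cause of all changes made by both treatments: 40 probes past an adjusted p of 0.001 and 0.5 on the log2 scale in both comparisons went opposite ways, where 7.79 false calls were allowed, and 1192 went the same way. This count does not cover a shared agent whose effects change direction with strength. For the 23 NF-kB genes an agent shared by both preparations, for example a bacterial product, cannot be told apart from an effect of CCN2 and GDF15 themselves, because the labels name no group that received such an agent, or an inactivated protein, alone. That CCN2 and GDF15 act through a common inflammatory pathway in these cells stays a hypothesis that these arrays leave untested.

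Lower macrophage markers after CCN2 were the next pattern, with 17 of 23 lower and 3 higher. A loss of sensitivity on the dimmer CCN2 arrays that acts alike on probes of the same brightness does not account for the fall. The list's median of -1.39 lay at percentile 0 of 10000 random lists of the same brightness, whose lowest median was -0.63. Camera had already called the list lower than other genes, and the random lists hold unrelated genes. The percentile is therefore no further test of the fall itself. A lower share of macrophages with unchanged transcripts in each would lower markers made by macrophages alone by a common amount. The members' log2 changes had an SD of 1.8592, against a median SE of 0.0913, and ran from -5.10 for C1qc to 2.48 for Clec4n. Whether other cells in the cultures made some of these markers was not tested. The spread therefore cannot exclude unchanged transcripts in each macrophage. None of the 23 members is held by another list, and all 23 were detected on all 4 control arrays, with C1qb at 12.18 on the log2 scale. A smaller number of macrophages together with a changed state of those present may underlie the pattern, and the arrays do not separate these.

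Lower cell cycle genes after both treatments were the last pattern. A loss of sensitivity on the treated arrays that acts alike on probes of the same brightness does not account for the fall. The medians of both lists lay at percentile 0 of 10000 random lists of the same brightness in both comparisons. They were -1.07 and -0.91 for S phase and -1.19 and -1.19 for G2 and M phase. These percentiles have the limits given for the macrophage markers. Whether fewer fibroblasts or fewer cells of another type were cycling was not tested.

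Over the levels of the named genes and 2 measures of array brightness, 25 of 528 groups of 4 arrays (4.73%), all of gene levels, held an array that stood far from the other 3, and chance gives about 5%. The share of the group's range that separated such an array from its nearest neighbour follows in brackets after the normalized log2 level and the range of the other arrays. Control replicate 1 had Vcan at 4.49 against 4.96 to 5.05 (0.854). Control replicate 2 had Ifit2 at 8.44 against 8.30 to 8.31 (0.909) and Ret at 4.20 against 4.27 to 4.28 (0.929). Control replicate 3 had Cyp51 at 8.99 against 9.26 to 9.30 (0.883), Gucy1a1 at 12.12 against 11.93 to 11.95 (0.878) and Isg15 at 7.76 against 7.93 to 7.95 (0.857). Control replicate 4 had Ankrd1 at 9.35 against 9.21 to 9.23 (0.888), C1qb at 12.29 against 12.14 to 12.16 (0.874) and Ogn at 12.94 against 12.75 to 12.78 (0.874). It also had Tcf21 at 11.04 against 11.27 to 11.30 (0.88), Tfrc at 7.99 against 8.19 to 8.23 (0.862) and Tnxb at 9.14 against 9.42 to 9.45 (0.899). CCN2 replicate 1 had Cldn5 at 7.04 against 6.72 to 6.77 (0.845) and Itga11 at 7.90 against 7.59 to 7.61 (0.927). CCN2 replicate 2 had Aldh1a1 at 6.77 against 7.17 to 7.20 (0.937), Ccn2 at 11.58 against 11.78 to 11.82 (0.835) and Hspb8 at 11.04 against 10.97 to 10.98 (0.833). It also had Il7r at 5.79 against 5.32 to 5.39 (0.851). CCN2 replicate 4 had Tnc at 9.45 against 9.84 to 9.88 (0.921). GDF15 replicate 2 had Acod1 at 7.84 against 7.21 to 7.30 (0.859), Cemip at 12.05 against 12.34 to 12.40 (0.835) and Cxcl2 at 7.79 against 6.92 to 7.05 (0.844). GDF15 replicate 3 had Fos at 8.31 against 8.71 to 8.78 (0.848) and Tfrc at 7.68 against 7.56 to 7.57 (0.869). GDF15 replicate 4 had Lss at 8.84 against 8.41 to 8.46 (0.881). Ret was detected on no control array, so its level there lay at background.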

How the results depend on the processing

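No setting here was added after the result was seen. A slide block was not run because slide positions were not analysed here. No paired analysis was run because the labels give the groups no shared replicate numbers. The order of the replicates on the third principal component was not modelled either, so it stays in the spread of the fit. Signal over background limits dim probes: the offset makes their changes smaller than they are, and 24836 probes were not tested.

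With 1 probe per gene before the fit, 6322, 2679 and 5262 genes changed for CCN2, GDF15 and GDF15 against CCN2, a smaller number because fewer probes were tested. In all other settings the counts stayed within 1.5 times, and leaving out single arrays gave 9659 to 10861, 3153 to 4113 and 7686 to 8542. With an estimated correlation 8 lists shifted after GDF15, and with fry, which does not compare a list with other genes, 23 shifted after GDF15 and 29 between the treatments. The covariance of both responses was 0.126 without background correction and 0.126 with the authors' processed values, 0.1805 with median scaling, 0.1091 with an offset of 50, 0.0811 without the detection filter, 0.2144 with the stricter filter, and 0.1709, 0.1713 and 0.1728 with the controls split in 3 ways, each the mean over both assignments of the control pairs to the treatments. The offset shrinks changes and the filters alter which probes enter, and the other causes were not tested.

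Of 51 list shifts, 44 kept their call in all 19 other settings of normalization, filter, samples and left-out arrays, and no called list changed direction. In the matrix proteins (0.105), fibroblast markers (0.1), bone and cartilage genes (0.0527) and macrophage markers (0.125) the call after GDF15 ended with median scaling, with adjusted p in brackets. Macrophage markers after GDF15 also missed the threshold with the stricter filter (0.0646), in a fit of the compared groups (0.0538), and without GDF15 replicate 3 (0.0866), CCN2 replicate 1 (0.0514) or CCN2 replicate 4 (0.0523). Collagen processing and crosslinking ended with the stricter filter after CCN2 (0.0566) and between the treatments (0.0687), and there also without GDF15 replicate 4 (0.0546). Bone and cartilage genes ended without the detection filter (0.106 after CCN2, 0.501 after GDF15). In all, 14 list calls were lost and 26 gained over 1767 list values. Median scaling brought past the threshold, each as higher, matrix proteases and inhibitors (0.0458), heat shock genes (0.0276) and SRF and YAP immediate genes (0.0276) after CCN2, and collagen processing (0.0299), NRF2 antioxidant genes (0.0339) and angiogenic and growth factors (0.0243) after GDF15. Heat shock genes after CCN2 were called without background correction (0.0463), with the authors' processed values (0.0463), an offset of 50 (0.0468), no detection filter (0.0231) and a fit of the compared groups (0.0345). TGF-beta SMAD2/3 targets between the treatments were called without background correction (0.043), with the authors' processed values (0.0431), an offset of 50 (0.0462) and no detection filter (0.0422). Without the detection filter SRF and YAP immediate genes after CCN2 (0.0361) and collagen processing after GDF15 (0.0488) passed too. Calls gained by leaving out 1 array were SRF and YAP immediate genes after CCN2 without CCN2 replicate 1 (0.0391) or 2 (0.0459), cardiomyocyte markers without CCN2 replicate 3 (0.0366), NRF2 antioxidant genes after GDF15 without GDF15 replicate 1 (0.04), TGF-beta SMAD2/3 targets between the treatments without GDF15 replicate 3 (0.0486), and heat shock genes after CCN2 without CCN2 replicate 3 (0.0366) or 4 (0.0493) or GDF15 replicate 3 (0.0475) or 4 (0.0404). The cause was not tested.

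Of 5235 values of named genes under other settings, 5196 kept their direction and side of the threshold, 31 lost the threshold and 2 passed it newly, Mbp after GDF15 with median scaling (adjusted p = 0.0335) and without GDF15 replicate 3 (0.0339). Signs turned only where no threshold was passed: Ccl6 after CCN2 was at -0.1206 with median scaling, and without single arrays Acta2 after GDF15 ran from -0.0048 to 0.0684 and Col1a1 from -0.0179 to 0.0993. With the trended robust variance model Cald1 and Insig1 after GDF15 lost their calls (adjusted p = 0.117 and 0.118). Calls lost without 1 array were Sdhc after CCN2 (adjusted p up to 0.146, without control replicate 4, and lost for 10 of the 12 arrays), Eng after CCN2 (without control replicate 2, 0.085, or 3, 0.113, or CCN2 replicate 1, 0.0891, or 3, 0.121), Cald1 after GDF15 (without control replicate 1, 0.113, 2, 0.0836, or 3, 0.0597, or GDF15 replicate 2, 0.0886, or 4, 0.11) and Insig1 after GDF15 (without control replicate 1, 0.128, or 2, 0.105, or GDF15 replicate 2, 0.0932, or 4, 0.11). The cause was not tested.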

Other observations

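In a search chosen after seeing the data, genes whose symbols share a stem were tested as families with camera, 185 families with at least 8 measured members each. Among the Ccl chemokines, 12 of 17 rose after GDF15 and 3 fell (adjusted p = 4.69e-10, but adjusted p = 0.467 with an estimated correlation), and 11 rose and 4 fell after CCN2, where the family did not pass (adjusted p = 0.0766). Ccl2 rose by 3.99 (SE 0.11) after CCN2 and by 2.71 (SE 0.11) after GDF15, and Ccl3 by 4.26 (SE 0.10) and 1.94 (SE 0.10). Ccl6 rose by 2.01 (SE 0.090) after GDF15 and was at 0.08 (SE 0.090) after CCN2, not past the threshold and at -0.12 there with median scaling. Ccl12 changed by -1.93 (SE 0.099) after CCN2 and was at 0.18 (SE 0.099) after GDF15, not past the threshold.

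All 9 Cxcl chemokines rose after CCN2 (adjusted p = 4.44e-07) and 6 rose after GDF15 with none lower (adjusted p = 1.93e-05). With an estimated correlation neither call held (adjusted p = 0.601 and 0.467). Cxcl1 rose by 4.92 (SE 0.11) and 2.57 (SE 0.11), Cxcl16 by 2.50 (SE 0.088) and 0.80 (SE 0.088), and the stromal chemokine Cxcl12 by 0.84 (SE 0.10) and 1.10 (SE 0.10). Cxcl9 was at least 4.29-fold higher after CCN2 and was detected on no control or GDF15 array. Of 41 genes with the symbol stem Il, mostly interleukins and their receptors, 15 rose and 4 fell after GDF15 (adjusted p = 0.00692, but adjusted p = 0.249 with an estimated correlation), with a family median of 0.12, and 19 rose and 11 fell after CCN2 (adjusted p = 0.366). The antagonist Il1rn rose by 2.37 (SE 0.11) and 1.81 (SE 0.11) and the receptor Il7r changed by -1.53 (SE 0.11) after CCN2 and by 0.48 (SE 0.11) after GDF15. With median scaling these families kept their direction in both comparisons with control, and the Ccl family after CCN2 had adjusted p = 0.00185.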
